A study of Rattus norvegicus with 24 samples.

How the data were processed

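RNA was measured in the hippocampus of 24 male Sprague-Dawley rat samples, with 1 library each, in a 2 by 2 design of training and corticosterone. Per the labels' protocols, total RNA was extracted from dissected, snap-frozen hippocampus, messenger RNA was enriched, and stranded libraries were sequenced as paired ends on a DNBseq instrument. Each library was placed in its group by its title, which gives a sample number, the training state and the treatment. There were 7 untrained vehicle, 6 untrained corticosterone, 5 trained vehicle and 6 trained corticosterone libraries. The labels give neither the training task, the dose nor the time of sampling, and no batch. They number the samples but do not state that each came from a separate rat, so p-values measure the spread between these samples. The column of sample 41, labelled untrained vehicle, stands among the trained vehicle columns of the count table. It was kept in the group its label gives, and the count of called genes in each contrast was also computed without it.

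The authors deposited 1 table of raw counts per gene, with whole numbers for 32883 Ensembl rat gene identifiers and 5 summary rows of the read counter. Per the submitters' processing notes, FastQC, MultiQC, STAR 2.7.0b and HTSeq 0.6.1 were used with genome build rn6. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping or antisense genes, and of genes with near-identical copies, are uncertain. The summary rows were left out of library sizes and tests. On average over the 24 libraries they held 22.0% of the column total as reads in no gene, 12.8% as reads aligned to several places, 3.31% as not aligned, 0.576% as ambiguous and 0.25% as low quality. The remaining 61.0% were assigned to genes, with a range of 59.8% to 62.6% over libraries. No molecular identifiers are named, so the counts are of reads, and reads copied from 1 molecule cannot be told apart. A read here is a unit that the read counter counted, which for these paired-end libraries may be a read pair. Intervals cover the spread between libraries and the sampling of reads.

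The identifiers are not paired with gene names in the count table. None of them (0) matched the reference table of 47357 rat genes of assembly GRCr8, whose Ensembl column held 0 entries. The 30 gene lists and cell type marker lists fixed before the data were examined, and the 10 genes always to be named, could therefore not be looked up, and no gene function is given. Checks of GC content and gene length are void for the same reason. The naming rule asked for called genes with a mean of at least 1 CPM and the smallest p. In place of named symbols, it was applied to identifiers and limited to 2 higher and 2 lower genes of the corticosterone effect averaged over training. Other single genes are described by their rank without an identifier.

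Genes with low counts were removed with filterByExpr by group, which left 14838 genes. Of the others, 9694 had 0 counts in every library. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F-test, glmQLFit and glmQLFTest) in R 4.3.3. One model held the 4 group means of all 24 libraries, and 7 contrasts were taken from it. These were the corticosterone effect averaged over training and within each training state, the training effect averaged over treatment and within each treatment, and the interaction. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are Wald errors from the fit, and 95% intervals use the quasi-likelihood degrees of freedom. Levels in CPM, read counts scaled to a common library size, use TMM-scaled totals. Principal components were taken from log2 CPM with a prior count of 2. A response score, added after the data were examined, was the mean over genes of the signed, gene-centred log2 CPM. It was built from the genes called in 1 training state and computed in the libraries of the other, then tested with an exact two-sided permutation test. A two-sided permutation test with 1e+05 resamples compared 11 library measures between treatments and between training states, which gave a family of 22 tests.

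Total counts in genes ranged from 13760331 to 16765088 per library, with a median of 15754782. At this depth the median half-width of the 95% interval on the log2 scale was 0.12 for the effects averaged over the other factor and 0.24 for the interaction. No pair of libraries within a group had counts as close as sampling noise, since the smallest chi-square per degree of freedom was 4.09. The scripts were tested on simulated data with 200 changed genes in each contrast, drawn from genes with a mean of at least 1 CPM. Genes were simulated independently, without the variation that libraries share across genes. Recovery below 1 CPM, with shared variation, or with fewer changed genes was not tested. For the corticosterone effect averaged over training, with 14770 genes, they recovered 72% of genes changed 1.25-fold, 80% of those changed 1.5-fold and 100% of those changed 2-fold. Averaged over treatment, the training effect was recovered in 64%, 96% and 100% of genes at these folds, with 14757 genes. The interaction was recovered in 26%, 58% and 80%, with 14747 genes.

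Alternatives fixed before the data were examined were DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), robust empirical Bayes, only the 2 groups compared, the sample number as a covariate, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. DESeq2 was fitted to 23184 genes, without the filter on low counts. Its default filtering by mean count was left on when p-values were adjusted, which can drop genes with low counts from the adjustment. The number of genes it adjusted over was not recorded. Its results therefore differ from the main fit in both the test and the gene set. Fits with 2 and 3 surrogate variables or with runs of sample numbers as a block were added after seeing the data. So were all alternatives for the response score, the first principal component and the number of genes detected.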

Results

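Hippocampal gene expression was measured by RNA-seq in rats that had or had not undergone training and had received corticosterone, the main glucocorticoid hormone of the rat, or vehicle. The study addresses how glucocorticoids enhance the formation of memory. The 2 factors gave 4 groups of 7 untrained vehicle, 6 untrained corticosterone, 5 trained vehicle and 6 trained corticosterone libraries. Total counts in genes were 15378716 ± 851457 (SD, n = 7), 15495329 ± 482829 (SD, n = 6), 14764536 ± 1141567 (SD, n = 5) and 16090839 ± 371340 reads (SD, n = 6) in these groups, in that order. Between 18085 and 18531 genes had at least 1 count in a library. The genes are given by identifier because the count table does not pair them with names.

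The first comparison asked which transcripts differed between corticosterone and vehicle, averaged over both training states. ENSRNOG00000017198 was higher in all 12 corticosterone libraries than in any of the 12 vehicle libraries. Its level was 1.05 ± 0.302 CPM in untrained vehicle (SD, n = 7), 5.44 ± 0.988 CPM in untrained corticosterone (SD, n = 6), 1.27 ± 0.399 CPM in trained vehicle (SD, n = 5) and 5.89 ± 2.20 CPM in trained corticosterone libraries (SD, n = 6). This is a 4.86-fold rise (log2 fold change 2.28, SE 0.17, edgeR adjusted p = 2.38e-08). ENSRNOG00000025121 rose 3.11-fold (log2 fold change 1.64, SE 0.13, edgeR adjusted p = 2.95e-08) and was also higher in 12 of 12 corticosterone libraries than in every vehicle library. Its level went from 2.03 ± 0.291 CPM to 6.34 ± 1.26 CPM in untrained rats (SD, n = 7 and 6) and from 1.91 ± 0.243 CPM to 5.96 ± 2.01 CPM in trained rats (SD, n = 5 and 6). Raw counts behind these values ranged from 11 to 150 reads for the former gene and from 25 to 160 reads for the latter.

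Among the genes that fell, ENSRNOG00000024207 had a log2 fold change of -0.35 (SE 0.05, edgeR adjusted p = 0.000263), and 11 of 12 corticosterone libraries lay below every vehicle library. It was at 15.5 ± 1.44 CPM in untrained vehicle (SD, n = 7), 12.3 ± 1.02 CPM in untrained corticosterone (SD, n = 6), 15.5 ± 1.54 CPM in trained vehicle (SD, n = 5) and 12.1 ± 0.533 CPM in trained corticosterone libraries (SD, n = 6). ENSRNOG00000014096, a more abundant transcript, had a log2 fold change of -0.22 (SE 0.04, edgeR adjusted p = 0.000871), with 10 of 12 corticosterone libraries below every vehicle library. Its level was 95.1 ± 5.44 CPM against 81.7 ± 4.93 CPM in untrained rats (SD, n = 7 and 6), and 91.6 ± 7.36 CPM against 78.8 ± 3.10 CPM in trained rats (SD, n = 5 and 6).

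**Figure D1:**
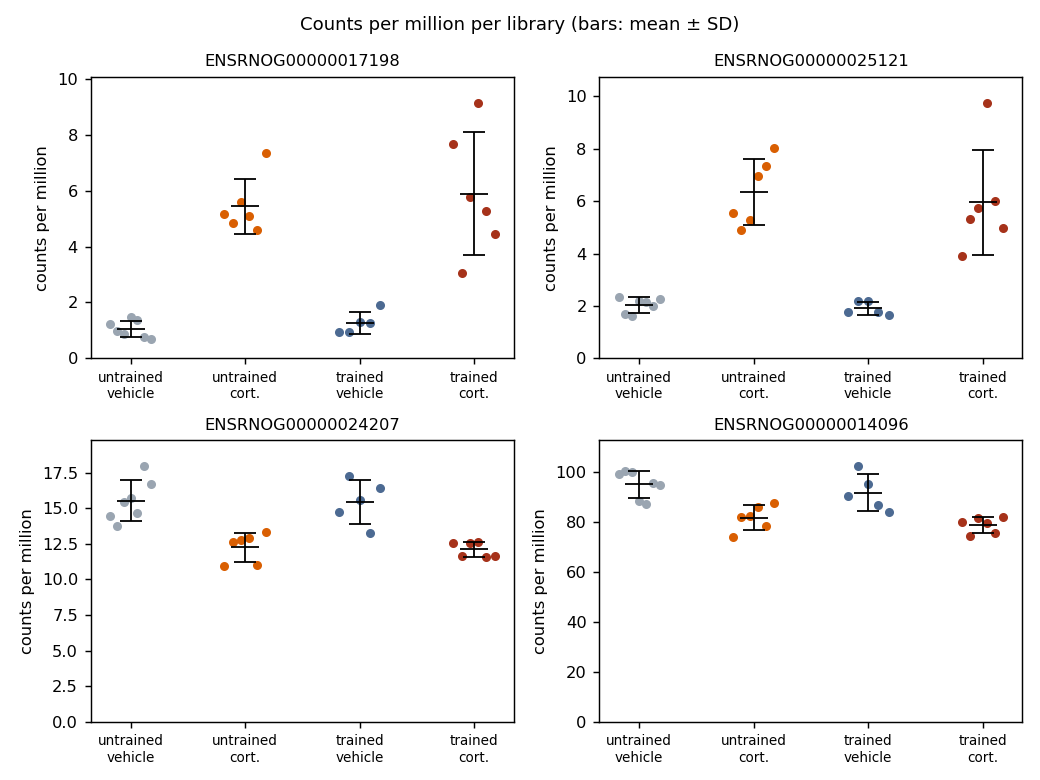
Levels in CPM of 4 genes in each of the 24 libraries, by group, with bars for the mean and SD; the vertical axes start at 0 and cort. stands for corticosterone. All 12 corticosterone libraries lay above all 12 vehicle libraries for ENSRNOG00000017198 and ENSRNOG00000025121, whereas 11 and 10 of them lay below all vehicle libraries for ENSRNOG00000024207 and ENSRNOG00000014096.

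In all, 138 of 14838 genes passed the threshold for corticosterone averaged over training, 101 of them higher and 37 lower. Of the genes that rose, 6 changed at least 2-fold, 21 between 1.5-fold and 2-fold and 74 by less than 1.5-fold, with a median log2 fold change of 0.39. Of those that fell, 0 reached 2-fold, 2 lay between 1.5-fold and 2-fold and 35 were below 1.5-fold, with a median log2 fold change of -0.28. Those that rose had mean levels from 1.02 to 384 CPM (median 24.5 CPM), and together they made up 4052 ± 96.6 CPM in vehicle libraries and 5025 ± 272 CPM in corticosterone libraries (SD, n = 12 each). The genes that fell had mean levels from 0.823 to 151 CPM and summed to 1328 ± 74.9 CPM and 1111 ± 52.2 CPM (SD, n = 12 each). These sums are over genes selected by the same test. The most abundant gene that rose went from 359 ± 14.1 CPM to 419 ± 26.8 CPM in untrained rats (SD, n = 7 and 6) and from 357 ± 9.50 CPM to 400 ± 34.1 CPM in trained rats (SD, n = 5 and 6), with a log2 fold change of 0.19 (SE 0.03, edgeR adjusted p = 0.00245).

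For 21 genes every corticosterone library was higher than every vehicle library, and for 1 gene every corticosterone library was lower. All of these genes were among the called ones. A random split into 12 and 12 libraries would separate a given gene, in either direction, in 7.4e-05% of cases. With 1 surrogate variable in the model, which follows the first principal component of the libraries, 114 genes passed, 102 of them shared with the 138. Without the library of sample 41, 109 passed, of which 105 were shared. With runs of sample numbers as a block, a fit added after seeing the data, 79 passed, 59 higher and 20 lower. The number of genes that fell was 57 with DESeq2, and between 20 and 24 when untrained corticosterone replicate 39 (20), untrained vehicle replicate 7 (22), trained corticosterone replicate 8 (22), untrained vehicle replicate 2 (24) or trained vehicle replicate 25 (24) was left out.

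Within untrained rats, 53 genes passed the threshold for corticosterone against vehicle, 48 higher and 5 lower. ENSRNOG00000017198 (log2 fold change 2.36, SE 0.24, edgeR adjusted p = 2.35e-06) and ENSRNOG00000025121 (log2 fold change 1.64, SE 0.17, edgeR adjusted p = 5.5e-06) rose, and ENSRNOG00000024207 (log2 fold change -0.34, SE 0.07, edgeR adjusted p = 0.0218) and ENSRNOG00000014096 (log2 fold change -0.22, SE 0.05, edgeR adjusted p = 0.0374) fell. The genes that rose had a median log2 fold change of 0.54, and 9 of them changed at least 2-fold. DESeq2 was fitted to 23184 genes without the filter on low counts, but its default filtering by mean count was kept in the adjustment. It called 87 genes in this contrast, 70 higher and 17 lower. The share of genes that rose was 80.5% there, against 90.6% in edgeR with 14838 genes. The edgeR count was 33 without untrained vehicle replicate 7, untrained vehicle replicate 41 or untrained corticosterone replicate 39, and 34 without untrained corticosterone replicate 29. In the fit of only the 2 untrained groups, ENSRNOG00000024207 (edgeR adjusted p = 0.078) and ENSRNOG00000014096 (edgeR adjusted p = 0.0755) did not pass. The former also missed the threshold with 3 surrogate variables (edgeR adjusted p = 0.0563) and in 4 fits that left out 1 library (edgeR adjusted p up to 0.0746), and the latter in 9 such fits (edgeR adjusted p up to 0.12).

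Within trained rats, 24 genes passed, all of them higher (0 lower). ENSRNOG00000017198 (log2 fold change 2.20, SE 0.25) and ENSRNOG00000025121 (log2 fold change 1.64, SE 0.19) rose, each with an edgeR adjusted p of 8.18e-05. The median log2 fold change of the 24 genes was 0.61, and 5 changed at least 2-fold. ENSRNOG00000024207 had a log2 fold change of -0.35 (SE 0.08, edgeR adjusted p = 0.0513) and ENSRNOG00000014096 one of -0.22 (SE 0.05, edgeR adjusted p = 0.104), and neither passed in this state alone. With DESeq2 both passed (adjusted p = 0.0113 and 0.0225), the former also passed with upper-quartile factors, a filter of 1 CPM or the sample number as a covariate (edgeR adjusted p = 0.0473, 0.0493 and 0.0469) and in 5 fits that left out 1 library (edgeR adjusted p down to 0.0202), and the latter with 3 surrogate variables (edgeR adjusted p = 0.0351). DESeq2, again without the filter on low counts but with its own filtering in the adjustment, called 60 genes, 46 higher and 14 lower. With edgeR, 13 were called when only the 2 trained groups were fitted and 14 without trained vehicle replicate 10. The fit with runs of sample numbers as a block called 11.

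Whether the corticosterone response differed with training was tested with the interaction. No gene passed (edgeR, 0 of 14838, smallest adjusted p = 0.378). An unadjusted p under 0.05 was found for 634 genes, where uniform p-values would give 742 on average. Random splits of the treatment labels within training state gave a median of 549. DESeq2 and limma called 0 genes as well, with 665 of 23184 and 718 of 14838 genes at an unadjusted p under 0.05. For ENSRNOG00000017198 the log2 fold change in trained minus that in untrained rats was -0.17 (SE 0.35, edgeR adjusted p = 0.98), and for ENSRNOG00000024207 it was -0.01 (SE 0.10, edgeR adjusted p = 0.993). The 95% interval of the interaction lay within 1.5-fold in either direction for 10860 genes (73.2%) and within 2-fold for 12977 genes (87.5%). The gene with the smallest interaction p had a log2 difference of 0.62 (SE 0.12, edgeR adjusted p = 0.378). It was at 6.36 ± 0.594 CPM and 4.99 ± 0.382 CPM without and with corticosterone in untrained rats (SD, n = 7 and 6), and at 5.02 ± 0.458 CPM and 6.08 ± 0.572 CPM in trained rats (SD, n = 5 and 6).

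All 138 genes called for corticosterone averaged over training had the same sign in untrained and in trained rats, as selection on their mean favours. In the direction of the call, their median log2 fold change was 0.33 in untrained and 0.32 in trained rats. The median difference between states was -0.02, with a median 95% half-width of 0.26 on the log2 scale for a single gene. The interval of the difference lay within 1.5-fold for 116 of the 138 genes and within 2-fold for 133. Adjusted over the list alone, 0 of the 138 passed for the interaction (5 at an unadjusted p under 0.05, smallest adjusted p = 0.998 by edgeR). Of the 138, 21 passed in both states, including ENSRNOG00000017198 and ENSRNOG00000025121, and 82 in neither state alone. The states share no library, and 0.0776 shared genes would be expected from independent lists of 48 and 24 higher genes.

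**Figure D2:**
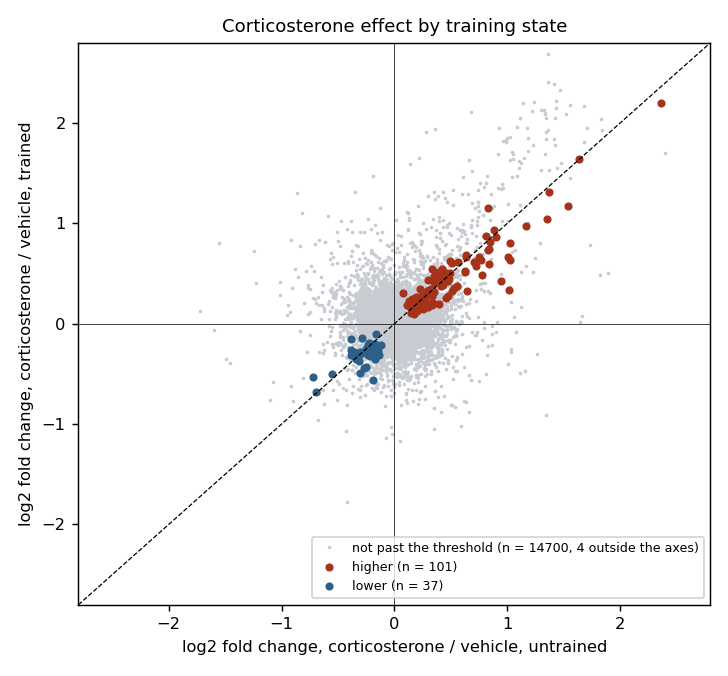
Log2 fold change of corticosterone over vehicle in untrained rats (horizontal axis) and in trained rats (vertical axis) for each tested gene, with the line of equal change dashed and 4 genes that were not called lying outside the axes. The 101 genes called higher (red) and the 37 called lower (blue) in the effect averaged over training all have the same sign in both states.

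The genes called in 1 training state were then followed in the libraries of the other, which had no part in the contrast that selected them. Of the 53 genes called in untrained rats, 53 had the same sign in trained rats, 51 passed there adjusted over the list alone and 21 passed over all genes tested (edgeR). All 24 genes called in trained rats had the same sign in untrained rats, where 24 passed adjusted over the list alone and 21 over all genes. The response score of the 53 genes was 0.271 ± 0.114 in trained corticosterone (SD, n = 6) and -0.238 ± 0.0583 in trained vehicle libraries (SD, n = 5). The difference was 0.510, and the groups did not overlap (exact two-sided permutation test, p = 0.00216). The score of the 24 genes was 0.359 ± 0.112 in untrained corticosterone (SD, n = 6) and -0.365 ± 0.0402 in untrained vehicle libraries (SD, n = 7), a difference of 0.724 without overlap (exact two-sided permutation test, p = 0.000583). These are the smallest p-values that the 462 and 1716 splits of the libraries can give. Scores are centred over all 24 libraries, and the gene dispersions were estimated from all 4 groups.

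**Figure D3:**
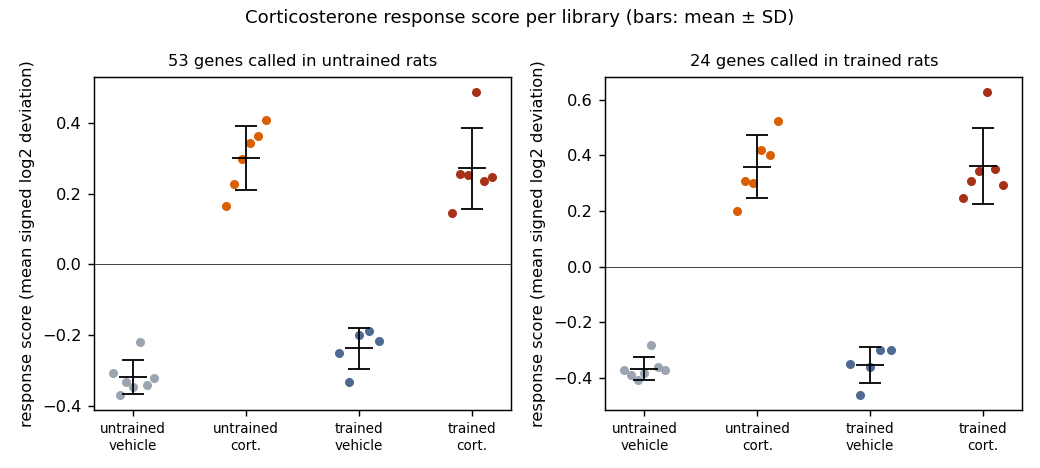
Response score (mean signed log2 deviation) per library for the 53 genes called in untrained rats (left) and the 24 called in trained rats (right), with bars for the mean and SD; cort. stands for corticosterone. In the state that did not select the genes, corticosterone libraries lay between 0.146 and 0.487 (left, trained) and between 0.201 and 0.523 (right, untrained), above all vehicle libraries.

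Across all 14838 genes, the log2 fold changes of corticosterone in the 2 training states had a Pearson correlation of 0.396 and a Spearman correlation of 0.104. Genes are not independent replicates, and the jackknife SE of the Pearson value over libraries was 0.361. Among the genes not called the Pearson value was 0.364. The Pearson value was 0.0319 without a filter on low counts (23189 genes) and 0.0574 with DESeq2, also fitted without that filter (23184 genes). It was 0.109, 0.126 and 0.174 with 1, 2 and 3 surrogate variables in the model, and 0.235 without trained vehicle replicate 10.

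The comparison of trained with untrained rats asked which transcripts differed with training. Averaged over treatment, no gene passed (edgeR, 0 of 14838, smallest adjusted p = 0.999). An unadjusted p under 0.05 was found for 485 genes, where uniform p-values would give 742 on average. Random splits of the training labels within treatment gave a median of 715. DESeq2 and limma also called 0 genes, with 487 of 23184 and 541 of 14838 genes at an unadjusted p under 0.05. The 95% interval of the training effect lay within 1.5-fold in either direction for 13530 genes (91.2%) and within 2-fold for 14522 (97.9%). The gene with the smallest p had a log2 fold change of 0.11 (SE 0.02, edgeR adjusted p = 0.999). It was at 34.7 ± 1.04 CPM in untrained and 39.3 ± 1.32 CPM in trained vehicle libraries (SD, n = 7 and 5), and at 35.7 ± 1.43 CPM and 36.5 ± 0.864 CPM in the corticosterone libraries (SD, n = 6 each). Of the genes named for corticosterone, the log2 fold change for training was 0.20 (SE 0.17, edgeR adjusted p = 0.999) for ENSRNOG00000017198 and -0.09 (SE 0.13, edgeR adjusted p = 0.999) for ENSRNOG00000025121, and neither passed. Over the 138 corticosterone genes, 4 had an unadjusted p under 0.05 for training and 0 passed adjusted over the list alone (edgeR, smallest adjusted p = 0.913).

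Within vehicle rats, 0 genes passed for training (edgeR, smallest adjusted p = 0.328), with 338 at an unadjusted p under 0.05, and DESeq2 and limma called 0 with 335 and 575. Within corticosterone rats, 0 passed (edgeR, smallest adjusted p = 0.812), with 903 at an unadjusted p under 0.05, and DESeq2 and limma called 0 with 925 and 657. Random splits of the training labels gave medians of 595 such genes in vehicle and 815 in corticosterone rats (edgeR). Intervals lay within 2-fold for 14051 genes in vehicle rats (94.7%) and for 13952 genes in corticosterone rats (94.0%).

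The first principal component carried 31.5% of the variance of log2 CPM, the second 9.32% and the third 7.84%. On the first component 8 libraries lay between 19.04 and 36.5, of which 6 were from corticosterone and 2 from vehicle rats, and 16 lay between -25.4 and 0.00267. The mean was 7.31 ± 24.6 in corticosterone and -7.31 ± 15.4 in vehicle libraries (SD, n = 12 each), a difference of 14.6 that did not pass a two-sided permutation test (p = 0.0981, adjusted p = 0.657 over 22 tests). Without untrained vehicle replicate 17 the unadjusted p was 0.0447, and without trained corticosterone replicate 3 it was 0.0449 (permutation tests). The gene with the largest loading was at 512 ± 1131 CPM in untrained vehicle, 1362 ± 1497 CPM in untrained corticosterone, 364 ± 774 CPM in trained vehicle and 1909 ± 2113 CPM in trained corticosterone libraries (SD, n = 7, 6, 5 and 6). Its log2 fold change for corticosterone was 1.90 (SE 1.16, edgeR adjusted p = 0.69). The number of genes with at least 1 count was 18382 ± 90.1 in corticosterone and 18230 ± 101 in vehicle libraries (SD, n = 12 each). This difference of 152 genes passed (two-sided permutation test, p = 0.00105, adjusted p = 0.0231 over 22 tests). With every library thinned to one depth it was 84.5 genes (SE 38.1, permutation test, p = 0.0378). Unthinned it was 240 genes in trained rats (exact permutation test, p = 0.00216, n = 6 and 5) and 77.2 genes in untrained rats (exact permutation test, p = 0.236, n = 6 and 7), and total counts were 670276 reads higher with corticosterone (permutation test, p = 0.0485, adjusted p = 0.533), by 1326303 reads in trained rats (exact permutation test, p = 0.0281) and 116613 reads in untrained rats (exact permutation test, p = 0.772).

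**Figure D4:**
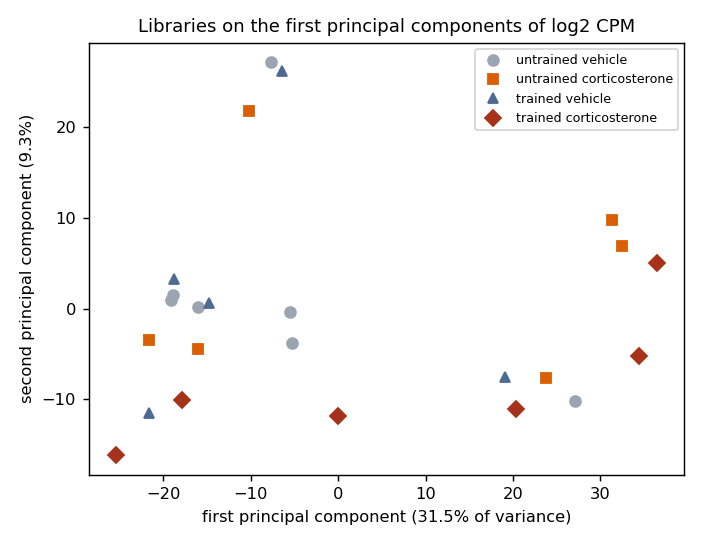
Position of each of the 24 libraries on the first (horizontal, 31.5% of the variance) and second (vertical, 9.32%) principal components of log2 CPM, with colours and symbols for the 4 groups. The 8 libraries to the right, at 19.04 to 36.5, come from all 4 groups.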

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

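The tests of the first principal component were chosen only after its result was seen. A library is given here when its distance to the nearest other library of its group, divided by the range of the group, was above the 95% critical value of Dixon's test. Of 36 combinations of group and measure, 5 met this, where chance gives about 1 in 20.

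Untrained vehicle replicate 17 lay at 27.04 on the first principal component, where the next vehicle library of its group was at -5.29. The component was higher on average in corticosterone libraries. Library depth is argued against, because the component kept 99.2% of its standard deviation after thinning every library to one depth. A shift in nearly every corticosterone-treated rat stays open. Of 12 corticosterone libraries, 4 lay below the vehicle median, but the SD was 24.6 in corticosterone and 15.4 in vehicle libraries against a difference of 14.6. With that spread, and with each treated rat's position without treatment unknown, the count cannot decide. Chance allocation of libraries along the component stays open (permutation p = 0.0981), although p was 0.0447 without this library and 0.0449 without trained corticosterone replicate 3. The component as the source of the corticosterone calls is argued against, since 102 of the 138 calls passed with a surrogate variable that carried 99.4% of its within-group variance. The 36 calls that ended kept their sign, and their median absolute log2 fold change went from 0.240 (median SE 0.0547) to 0.217 (median SE 0.0564). The fold was smaller in 31, the SE larger in 28 and the ratio of fold to SE smaller in all 36. Selection on a lost call favours these changes, so they say nothing further about the component.

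The response score of trained corticosterone replicate 28 was 0.487, against 0.257 in the next library of its group, and its level of ENSRNOG00000025121 was 9.76 CPM against 6.02 CPM in the next. A few genes as the source are argued against, because this library was the most extreme of its group in 35 of the 53 scored genes. The ratio of gap to range fell from 0.676 to 0.564, below the critical value, once the first principal component was removed from every gene. This cannot decide whether the component accounts for the distance of this library, because the ratio also falls when the range of the group widens. A stronger response to corticosterone in this rat stays open and was not tested, as the labels give no measure of exposure for single rats. Without this library the score difference in trained rats was 0.423, and the log2 fold change of ENSRNOG00000025121 averaged over training was 1.54.

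ENSRNOG00000017198 was at 7.33 CPM in untrained corticosterone replicate 39, where the next library of the group was at 5.59 CPM. The response score of untrained vehicle replicate 27 was -0.281, where the next was -0.359.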

How the results depend on the processing

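Fits with 2 or 3 surrogate variables or with runs of sample numbers as a block, and the alternatives of the first principal component, the number of genes detected and the response score, were chosen after seeing the data. The count of genes called for corticosterone averaged over training was 138 in the main fit and, but for the block, went from 114 (1 surrogate variable) to 180 (DESeq2), and from 97 to 154 when each library was left out in turn. Counts for the 3 training contrasts and the interaction were 0 under every alternative run. DESeq2 was fitted without the filter on low counts, but its default filtering by mean count was kept in the adjustment. It called 87 genes in untrained and 60 in trained rats, including all 53 and all 24 of the edgeR calls. It called 57 lower genes in the effect averaged over training. The cause was not tested. The fit of only the 2 trained groups called 13 genes, from fewer libraries. Leaving out each library gave 33 to 62 genes in untrained rats and 14 to 27 in trained rats. The Pearson correlation between training states was 0.0319 without a filter, from more genes tested (23189), and 0.0574 with DESeq2, also without the filter (23184 genes). It was 0.109, 0.126 and 0.174 with 1, 2 and 3 surrogate variables, and between 0.235 and 0.567 with each library left out. The first component's difference between treatments was 11.8 to 17.7 with each library left out, and the difference in genes detected was 77.2 within untrained and 240 within trained rats.

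ENSRNOG00000017198 and ENSRNOG00000025121 kept their calls under every alternative in all 3 corticosterone contrasts, with adjusted p up to 0.0109 (only the 2 trained groups). ENSRNOG00000024207 and ENSRNOG00000014096 kept theirs in the effect averaged over training, with adjusted p up to 0.00493 and 0.00267. Within 1 training state both crossed the threshold under some alternatives, with adjusted p up to 0.092 and 0.12 in untrained rats. In untrained rats both lost their calls in the fit of only 2 groups (0.078 and 0.0755), and ENSRNOG00000024207 lost its call with 3 surrogate variables (0.0563), with the block (0.092) and without untrained vehicle replicate 32 or 41 or untrained corticosterone replicate 4 or 29 (adjusted p 0.0511 to 0.0746), and ENSRNOG00000014096 without untrained vehicle replicate 2, 7, 17, 32 or 41 or untrained corticosterone replicate 4, 9, 14 or 29 (0.0666 to 0.12). In trained rats ENSRNOG00000024207 passed with upper-quartile factors (0.0473), the filter of 1 CPM (0.0493), DESeq2 (0.0113) and the sample number as a covariate (0.0469), and without trained vehicle replicate 25, untrained vehicle replicate 7 or 32, or untrained corticosterone replicate 4 or 29 (0.0202 to 0.0497), and ENSRNOG00000014096 passed with DESeq2 (0.0225) and 3 surrogate variables (0.0351). The response score differences kept their sign and their exact test call, from 0.386 to 0.614 in trained and 0.469 to 0.951 in untrained rats. The groups share no sample number, but most numbers rotate through the groups in fives, so these 8 runs, with sample 41 joined to the last, were fitted as a replicate block. It called 79, 35 and 11 genes for corticosterone averaged over training, in untrained and in trained rats. Over all genes the runs showed little pairing of the samples. Of 28 pairs within a run, 7 had correlated deviations over 0.1, and 3 of 23 libraries had their closest library of another group in their own run. As these correlations were taken over all genes, they cannot exclude an effect of the runs on part of the genes. The alternatives planned for gene lists and marker scores were not run, as the identifiers are not paired with names. Depth and spread limit small effects. Of simulated genes of at least 1 CPM at the smallest fold, 26% were recovered for the interaction and 72% for corticosterone averaged over training.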

Other observations

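The test of an additional tissue was chosen only after the component was seen, and averaging the thinning over 20 draws, with a margin of 1 SE for reading its result, only after the value of a single draw was seen. A block of genes varied strongly between libraries. The 200 genes with the largest absolute loadings on the first principal component held 75.3% of its squared loadings, and 198 of them moved in the same direction. Of the 200, 1 was among the genes called for corticosterone, which is near the share over all genes tested (138 of 14838). Their summed level ranged from 659 CPM to 10880 CPM over the 24 libraries, and the gene with the largest loading alone ranged from 5.70 CPM to 4674 CPM. The 8 libraries high on the component were 4 untrained and 4 trained. Across genes, the loading and the log2 fold change of corticosterone had a Pearson correlation of 0.747, which the higher mean of the component in corticosterone libraries produces by construction. As a hypothesis, part of the dissections may have held additional tissue whose transcripts are scarce in the others, in which case nearly all strongly loaded genes should move one way. That was so for 99% of the 200, but a set of genes switched on together within the hippocampus would give the same value. Marker genes could not be looked up, and the source stays open.

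Random splits of the treatment labels within training state, 100 in all with the real one, tested whether the counts for corticosterone could come from chance. For corticosterone averaged over training, 1 split (the real one) gave as many as 138 genes, and the highest other gave 4. In untrained rats 1 split gave 53 or more and the highest other gave 2. In trained rats 2 splits gave 24 or more. Chance is excluded at the 5% level for these 3 counts. The other split in trained rats called 297 genes and had the largest difference on the first principal component of the 99 others (30.1, against 16.5 in the real split). Whether that structure of the samples gave its calls was not tested. No other split gave any gene called in both states (0, against 21).

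For the interaction and the 3 training contrasts the observed count was 0, which all 100 splits reach whatever they give, so the splits test nothing about these counts. The highest others were 1 for the interaction and, with the training labels split within treatment, 918, 0 and 963 genes for training averaged over treatment, in vehicle and in corticosterone rats. The splits with 918 and 963 genes were those with the largest difference on the first component (29.8 and 45.0), and whether it gave their calls was not tested. For training averaged over treatment, 485 genes had an unadjusted p under 0.05. This lay below the median of 715 over the other splits, and 16 of 100 splits gave as few. For the interaction, the 634 such genes lay above the median of 549, and 38 of 100 splits of the treatment labels gave as many. In trained rats 1053 genes had an unadjusted p under 0.05 for corticosterone, and 15 of 100 splits gave as many, up to 2504. The number was 948 in untrained rats, where 23 of 100 splits gave as many, and 1372 averaged over training, where 8 of 100 did. Chance is not excluded for any of these numbers. For the correlation of 0.396 between training states, 5 of 100 splits gave as high a value, up to 0.488, so chance is not excluded.

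More genes were detected in corticosterone than in vehicle libraries, by 152. The first principal component as the whole cause is argued against, since a difference of 127 genes remained after its linear trend was removed (permutation p = 0.00193). How much of the difference of 152 genes library depth accounts for cannot be told. Thinning every library to 13760331 counts, averaged over 20 draws, left a difference of 84.5 genes (SE 38.1, permutation p = 0.0378), or 55.7% of the original. By the rule fixed before, which had no margin, this value would argue against depth. Unthinned, the effect was 163 genes larger in trained than in untrained rats (permutation p = 0.0346, adjusted p = 0.125 over 4 measures), which did not pass. Total counts were 1326303 reads higher with corticosterone in trained rats and 116613 in untrained rats. This difference between states was not tested after thinning, so depth may account for part of it.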
